A study of Mus musculus with 6 samples.

How the data were processed

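RNA was measured in 6 bulk tumours, 3 from wild-type (WT) mice and 3 from mice lacking Thbs2 (Thbs2KO). Each tumour grew in the rectum from implanted mouse tumour organoids, which are cultured tumour epithelium carrying mutations in Apc, Trp53, Kras and Tgfbr2. Per the labels' protocols, tissue was homogenised in TRIzol, total RNA was purified on columns with DNase digestion, and libraries came from version 2 of Illumina's TruSeq RNA kit, which does not mark strand. Reads from overlapping genes on opposite strands could therefore not be told apart.

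Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.3a, RSEM and the mouse build mm10 were used; the version of RSEM and the annotation release are not given in the sources used here. The deposited table holds expected counts, the estimated counts that RSEM assigns to each gene, as whole numbers that were not scaled between libraries. RSEM shares reads that match several places between genes by estimation, so values of near-identical genes depend on that estimate. Expected counts were rounded to whole numbers before testing, which left the deposited values as they were. The table held 55401 genes with versioned Ensembl identifiers and symbols, of which 26982 had any count. Of these identifiers, 54349 matched GENCODE release M21 for GRCm38, the assembly that mm10 denotes, when versions were ignored. Coordinates are from that release.

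Total expected counts ranged from 16338011 to 24771255 per library. At this depth 1 CPM before normalisation stood for 16.3 to 24.8 counts, so for most genes named here the spread between tumours, and not counting error, set the precision. The common biological coefficient of variation was 0.357. Intervals given for genes with 1 to 3 counts in a group are 95% intervals and cover counting error only. Libraries of a group were compared before averaging. Their counts differed far beyond sampling noise, with a chi-square per degree of freedom of at least 26.8 for every pair, so each library counted as 1 replicate. The labels do not say outright that the 6 tumours came from separate animals; p-values therefore measure only the spread between these samples.

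Groups followed the genotype in the labels. Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM normalisation and the package's default expression filter, with genotype as the only term. The filter left 15382 genes. P-values were adjusted by the Benjamini-Hochberg method (FDR), with a threshold of 0.05. The standard error (SE) of a log2 fold change was derived from the F statistic. Levels are TMM-normalised CPM, computed here. Gene lists were written from textbook knowledge before the data were examined. The 38 lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 38 lists. Camera with a correlation estimated for each list and the rotation test fry were run beside it. Lists with under 4 measured members would not have been tested; none was that small. Each tumour's list score is the mean log2 CPM of the measured members.

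The rule for naming genes was also fixed before the data were examined. It took Thbs2; up to 10 genes per direction past the threshold with a mean of at least 1 CPM and no overlap between the groups, filled up by smallest p where fewer passed; and the members with the smallest p of each list, up to 4 for the main lists on immune cells, stroma and tumour that passed camera or had been singled out beforehand, and up to 3 for the others. Gene models without a given name, receptor and immunoglobulin segments and pseudogenes were counted but not named in the second part. Other genes are marked in the text as chosen after their values were seen.

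The procedure was tested on simulated data for this comparison, with counts drawn from the means, library sizes and estimated dispersions of the 15382 genes. Changed genes were picked only from those above a minimum mean count, so the shares recovered apply to such genes. The test recovered 10.4% of 67 genes changed 2-fold, 71.6% of 67 changed 4-fold and 87.9% of 66 changed 8-fold, and 8 of its 121 calls were unchanged genes. A list shifted by 1 on the log2 scale was recovered, and 0 of 33 lists sharing no member with it were called. Each gene was drawn independently of the others. The simulation therefore cannot show how often camera calls lists whose genes move together, as they can in real tumours.

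Alternatives set before the data were examined were other scalings (RLE, upper quartile, library size only), other expression filters, other thresholds, limma-voom without and with sample weights, DESeq2 1.42.0, the replicate number as a block, the mean of the tumour epithelium genes as a covariate, another prior count, and leaving out each tumour in turn. Removing 2 ribosomal RNA-like genes, DESeq2, limma-voom and upper quartile factors for the Thbs2 level, and leaving out each tumour for counts of list members were added after seeing the data. No library or column was left out.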

Results

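Bulk RNA of rectal tumours was compared between WT and Thbs2KO host mice. Thbs2 encodes thrombospondin 2, a matricellular glycoprotein made mainly by fibroblasts. The implanted organoids were the same kind in both groups, so the genotype refers to the host. The question, from the title of the series, was how host Thbs2 bears on the immune environment of colorectal tumours. Each group had 3 tumours. Total expected counts were 17100135, 16609966 and 17612723 in WT replicates 1 to 3 and 16338011, 24771255 and 20022572 in Thbs2KO replicates 1 to 3. Between 21019 and 21631 genes had a count in each library.

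The first principal component of log2 CPM held 44.3% of the variance and separated the genotypes. The second held 25.4% and spread the tumours within both groups. Correlations across genes between tumours of a group ran from 0.943 to 0.973 in WT and from 0.916 to 0.954 in Thbs2KO. Thbs2KO replicate 3 stood apart in its content of ribosomal RNA-like reads. The gene CT010467.1, chosen after its values were seen, took 4.94% of its counts, against 0.126% to 0.749% in the other 5 libraries. Mitochondrial genes took 2.52% to 2.62% of counts in WT tumours and 1.65%, 2.04% and 2.53% in Thbs2KO replicates 1 to 3.

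Thbs2 (ENSMUSG00000023885.9; chromosome 17, 14665500 to 14694235, minus strand, GRCm38) was lower in every Thbs2KO tumour than in any WT tumour. WT tumours had 381, 953 and 812 CPM and Thbs2KO tumours 80.9, 87.4 and 237 CPM. The means were 716 ± 298 and 135 ± 88.3 CPM (SD, n = 3 each), so 18.9% of the WT level was left. The labels do not give the deleted part of the gene, and counts per gene cannot tell transcript of the implanted tumour cells from transcript of the targeted host allele. The log2 fold change was -2.41 with an SE of 0.53, and the edgeR quasi-likelihood test gave an FDR of 0.137, which missed the threshold. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 tumours allow. The nearest pair across the groups was Thbs2KO replicate 3, at 237 CPM, and WT replicate 1, at 381 CPM. Over 17 alternatives for the Thbs2 level the adjusted p ran from 6.80e-05 to 0.431, and it passed in 3 of them. DESeq2 was among these, with a log2 fold change of -2.40.

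Of 15382 genes tested, 11 passed an FDR of 0.05 in edgeR, 10 higher and 1 lower in Thbs2KO tumours. Among them were Isg15, Usp18 and Oas2, which are 3 of the 26 members of the type I interferon list. Galectin 9 (Lgals9, chromosome 11, 78962974 to 78984946) rose from 48.5 ± 1.35 to 233 ± 39.4 CPM, a log2 fold change of 2.26 with an SE of 0.19 (FDR 0.0277). The ubiquitin-like modifier Isg15 (chromosome 4, 156199424 to 156200818) rose from 6.76 ± 2.62 to 99.3 ± 24.1 CPM, by 3.87 ± 0.34 (log2, SE; FDR 0.0277). Usp18, the protease that removes Isg15 from proteins, rose by 2.21 ± 0.24, the RNA sensor Oas2 by 4.12 ± 0.45 and the interferon-inducible Ifi204 by 3.16 ± 0.33 (log2, SE). Apol9a and Apol9b, which are close relatives on chromosome 15, rose by 4.27 ± 0.43 and 3.43 ± 0.30. The prolactin family gene Prl2c3 rose by 5.16 ± 0.56, from 0.643 ± 0.154 to 23.2 ± 12.9 CPM. The share of each Apol9 gene, and that of Prl2c3 among its close relatives, depends on how shared reads were divided. The remaining 2 genes that rose were gene models without a given name.

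**Figure D1:**
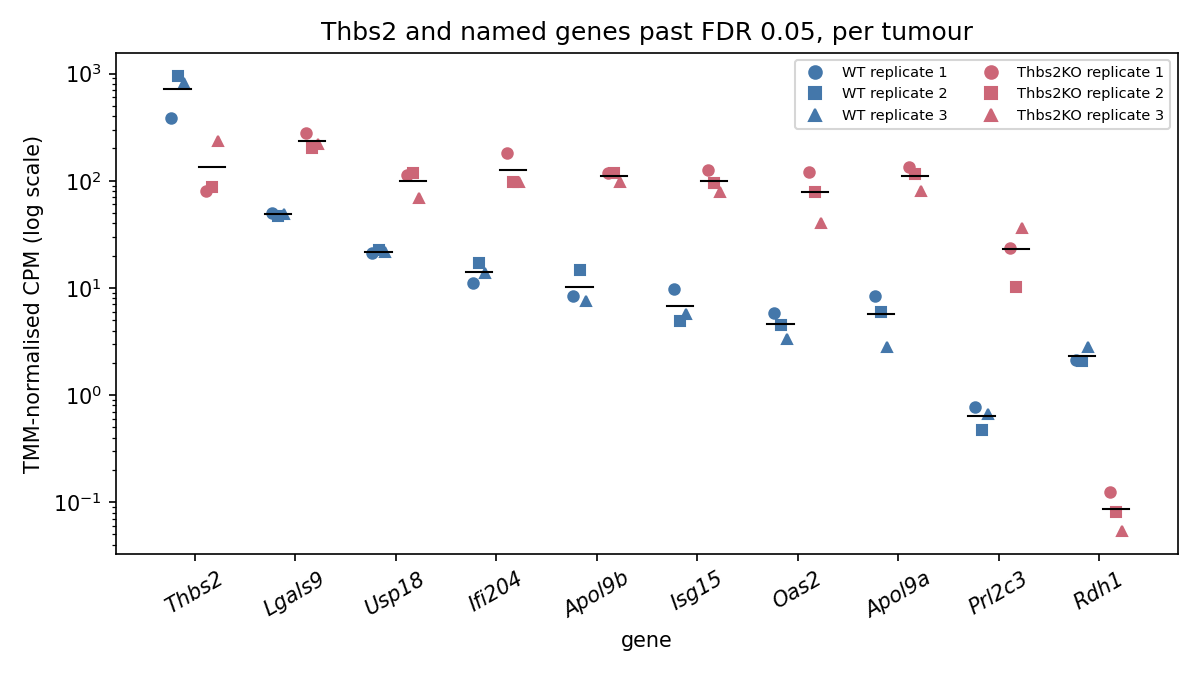
TMM-normalised CPM on a log axis of Thbs2 and the 9 named genes past FDR 0.05 in the 3 WT and 3 Thbs2KO tumours. Each point is 1 tumour and each line a group mean. The groups overlap in none of these genes, with Isg15 at 4.88 to 9.75 CPM in WT and 77.8 to 125 CPM in Thbs2KO tumours.

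The gene that fell was Rdh1 (ENSMUSG00000089789.1; chromosome 10, 127759721 to 127768297), a retinol dehydrogenase, with 2.33 ± 0.403 CPM in WT and 0.0862 ± 0.0356 CPM in Thbs2KO tumours. It rests on 123 counts in the WT and 5 in the Thbs2KO libraries. The gene Rdh16f1, chosen after its values were seen, starts inside it at 127759787. The values of both genes may therefore depend on how shared reads were divided, and whether their exons overlap was not checked. Genes that came next by p and missed the threshold included Ifi44, at 4.75 ± 1.63 and 83.9 ± 45.7 CPM (FDR 0.0516). The myelin gene Mpz had 2 counts in WT and 131 in Thbs2KO libraries, a ratio of 55.0 with a 95% counting interval of 14.9 to 459 (FDR 0.0590). Among lower genes that missed the threshold, the nuclear receptor Rorc had 6.79 ± 1.34 and 1.19 ± 0.177 CPM (FDR 0.0728). The intestinal stem cell factor Ascl2 had 11.6 ± 5.63 and 1.21 ± 0.558 CPM (FDR 0.0900) and the brush border enzyme Mgam 16.7 ± 3.07 and 3.77 ± 1.62 CPM (FDR 0.0988). Togaram2, Rassf10, Prr18, Cited1, Kif21a and Rp1 had log2 fold changes from -4.15 to -1.39, with an FDR of 0.114 to 0.118.

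The gene count depended on the tool, the expression filter and single tumours. An unadjusted p under 0.05 was found for 2376 genes, 1517 higher and 859 lower, where chance would give 769. The groups did not overlap in 3604 genes, or 23.4% of those tested, where chance gives 10%. DESeq2, which also uses its own filter, called 989 genes, all 11 edgeR calls among them, and limma-voom called 6. Without an expression filter edgeR called 116. Without WT replicate 1, 2 or 3 the edgeR count was 4, 0 and 0, and without Thbs2KO replicate 1, 2 or 3 it was 0, 26 and 12. With the tumour epithelium genes as a covariate it was 0.

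Genes induced by type I interferon, the antiviral cytokines interferon alpha and beta, were higher in Thbs2KO tumours as a group. All 26 measured members of the list had a higher mean, and in all 26 the groups did not overlap. All 26 rose when adjusted over the list alone, and 3 (Isg15, Usp18 and Oas2) when adjusted over all genes tested. The mean log2 fold change was 3.15, or 8.85-fold (camera FDR 2.59e-27). With an estimated correlation the adjusted p was 0.648. Tumour scores were 3.73, 2.98 and 2.88 in WT and 7.03, 6.22 and 5.35 in Thbs2KO tumours. In the list alone, all 26 genes also rose with any 1 tumour left out.

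Genes of interferon-gamma response and antigen presentation followed, with all 31 members higher on average and 27 rising when adjusted over the list alone, 0 over all genes. The mean log2 fold change was 2.46 (camera FDR 1.21e-15; adjusted p = 0.675 with an estimated correlation). The immunoproteasome subunit Psmb8 rose from 18.0 ± 4.63 to 68.1 ± 32.9 CPM when adjusted over the list alone. The proteasome activators Psme1 and Psme2 rose by 1.17 ± 0.28 and 1.45 ± 0.30 (log2, SE), and B2m, the light chain of MHC class I, by 1.97 ± 0.48, by the same criterion. Thbs2KO replicate 1 carried much of this change. Without it the mean was 1.39 and 23 members rose when adjusted over the list alone; without WT replicate 2 or 3 that count was 0.

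Macrophage and monocyte markers were higher in each Thbs2KO tumour than in any WT tumour by list score. Of 20 measured members, 19 had a higher mean, and 17 rose when adjusted over the list alone and 0 over all genes. The mean log2 fold change was 1.38, or 2.59-fold (camera FDR 1.68e-10; adjusted p = 0.648 with an estimated correlation). By the list-alone criterion the mannose receptor Mrc1 rose from 77.7 ± 14.2 to 220 ± 65.5 CPM, Adgre1 (F4/80) from 33.2 ± 2.34 to 85.9 ± 28.6 CPM and the complement gene C1qb from 146 ± 18.7 to 514 ± 240 CPM. C1qa rose by 1.75 ± 0.35 (log2, SE). Scores were 5.18 to 5.52 in WT and 6.31 to 6.78 in Thbs2KO tumours.

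T cell markers were higher on average, and most of that change came from 1 tumour. Of 20 measured members, 15 rose and 1, the kinase gene Zap70, fell when adjusted over the list alone, and 0 passed over all genes; Zap70 was chosen after its values were seen. The mean log2 fold change was 2.31 (camera FDR 5.40e-05; adjusted p = 0.676 with an estimated correlation). The co-receptor gene Cd8a had 0.836, 0.715 and 0.168 CPM in WT tumours and 32.4, 5.49 and 1.93 CPM in Thbs2KO tumours. Cd8b1 had means of 0.224 ± 0.241 and 5.80 ± 7.74 CPM, Cd6 of 1.07 ± 0.0994 and 6.74 ± 7.29 CPM and Cd247 of 0.511 ± 0.0981 and 2.99 ± 3.02 CPM. Tumour scores overlapped, at 1.07, 0.47 and 0.43 in WT and 3.96, 1.86 and 0.96 in Thbs2KO tumours (exact two-sided permutation p = 0.2; the smallest possible is 0.1). Without Thbs2KO replicate 1 the mean was 0.87 and 0 members passed over the list alone; that count was also 0 without WT replicate 1, 2 or 3. The log2 fold changes of Cd8a, Cd8b1, Cd6 and Cd247 went from 4.52, 4.63, 2.65 and 2.52 to 2.69, 2.54, 1.27 and 1.28 without Thbs2KO replicate 1.

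Cytotoxic effector and NK cell genes showed the same tumour on top. Of 9 measured members, 4 rose when adjusted over the list alone and 0 over all genes. The mean log2 fold change was 2.31 (camera FDR 0.0167; adjusted p = 0.676 with an estimated correlation). Granzyme B (Gzmb) had 0.387 ± 0.329 and 5.21 ± 5.72 CPM, the granule gene Nkg7 0.353 ± 0.395 and 9.06 ± 12.3 CPM, Cst7 0.305 ± 0.0451 and 2.20 ± 1.93 CPM and the chemokine Ccl5 2.11 ± 1.47 and 45.4 ± 71.5 CPM. The mean was 0.79 without Thbs2KO replicate 1 and 2.06 without WT replicate 3, and in both cases the list no longer passed. Without Thbs2KO replicate 1 the log2 fold changes of Gzmb, Nkg7, Cst7 and Ccl5 went from 3.73, 4.64, 2.81 and 4.42 to 2.29, 2.45, 1.81 and 0.96. Regulatory T cell and checkpoint genes had a mean of 1.64 (camera FDR 0.00108; adjusted p = 0.676 with an estimated correlation), which was 0.59 without Thbs2KO replicate 1. Of 13 measured, 2 rose when adjusted over the list alone. The checkpoint receptor Havcr2 rose by this criterion from 6.67 ± 1.79 to 23.8 ± 4.97 CPM, and Cd274, which encodes PD-L1, had a log2 fold change of 2.22 ± 0.55 (SE). Pdcd1 and Il2ra had 3.25 ± 1.08 and 2.33 ± 0.80. Without Thbs2KO replicate 1 the log2 fold changes of Cd274 and Pdcd1 were 1.30 and 1.31, and Il2ra was at 14.8 CPM in that tumour against at most 3.83 CPM in the other 5.

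**Figure D2:**
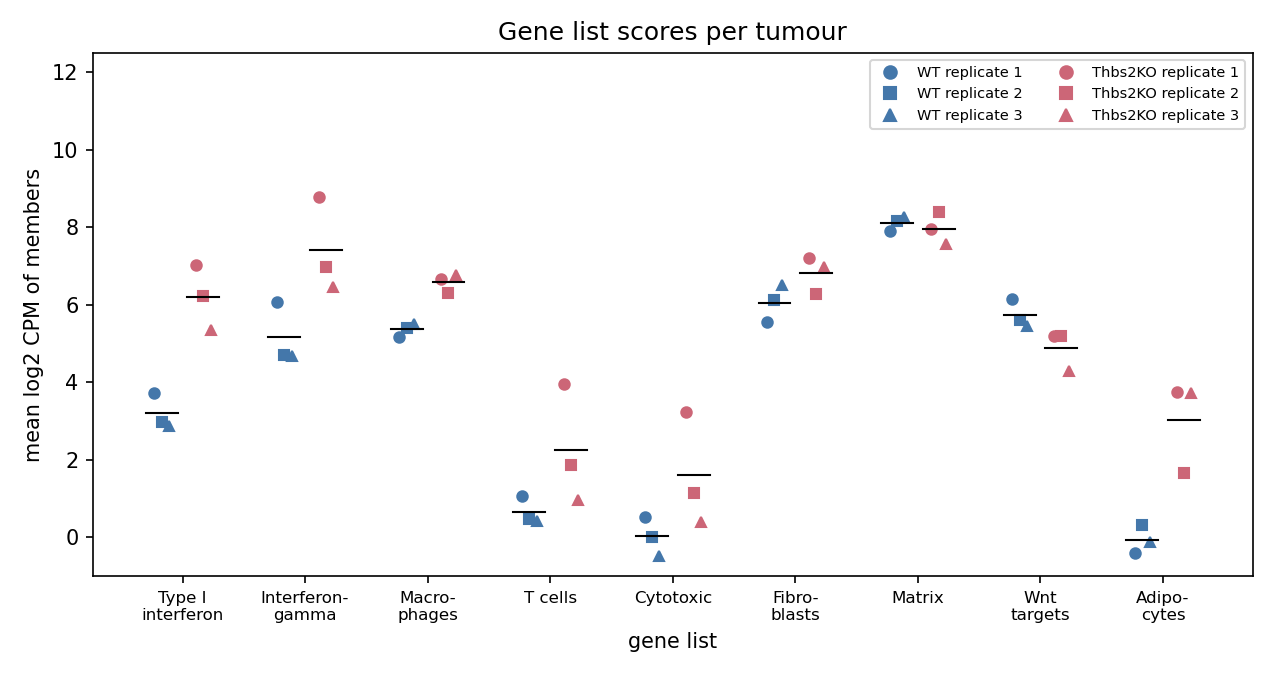
Mean log2 CPM of the measured members of 9 gene lists in each of the 3 WT and 3 Thbs2KO tumours, with lines at the group means. The groups do not overlap for type I interferon genes (2.88 to 3.73 in WT, 5.35 to 7.03 in Thbs2KO), while T cell scores overlap and are highest, at 3.96, in Thbs2KO replicate 1.

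Chemokine and cytokine genes were also higher. Of 26 chemokines, 9 rose when adjusted over the list alone, with a mean log2 fold change of 1.83 (camera FDR 3.79e-05; adjusted p = 0.648 with an estimated correlation). The monocyte attractant Ccl8 rose by this criterion from 13.6 ± 0.731 to 114 ± 53.7 CPM, and Cxcl1, Ccl7 and Cxcl16 had log2 fold changes of 1.82 ± 0.36, 2.94 ± 0.64 and 1.28 ± 0.29 (SE); that of Ccl7 was 1.95 without Thbs2KO replicate 3. Of 17 inflammatory cytokine genes, 4 rose when adjusted over the list alone, with a mean of 1.12 (camera FDR 1.36e-04; adjusted p = 0.675 with an estimated correlation). Tnf rose by it from 7.27 ± 0.572 to 19.9 ± 4.16 CPM, and Il1a had 6.19 ± 2.96 and 21.8 ± 5.65 CPM. Csf1 and Il6 had log2 fold changes of 0.60 ± 0.17 and 2.83 ± 0.82, and Il6 had 1.40 without Thbs2KO replicate 3. Neutrophil markers had a mean of 1.76 over 15 members, 0 of which passed alone (camera FDR 3.79e-05; adjusted p = 0.675 with an estimated correlation); it was 1.14 without Thbs2KO replicate 3, where S100a9 was at 150 CPM. Acod1, Retnlg and Trem1 had log2 fold changes of 3.06 ± 0.95, 3.68 ± 1.21 and 1.21 ± 0.45. Acod1 had 1.40 without Thbs2KO replicate 1, and Retnlg had 1.21 without Thbs2KO replicate 3.

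Immunoglobulin and other B lineage genes had a mean log2 fold change of 3.18 over 11 members, 4 of which rose when adjusted over the list alone (camera FDR 2.41e-05; adjusted p = 0.675 with an estimated correlation). The median was 1.665, and all 4 were immunoglobulin heavy chain genes. The B cell genes Cd79b, Cd79a and Blk, chosen after their values were seen, had 1.665, 1.002 and 0.119 and did not pass over the list alone. Ighg2c had 0, 0.0596 and 0.728 CPM in WT tumours and 1022, 39.4 and 147 CPM in Thbs2KO tumours, so it was highest in replicate 1, and Ighm had 4.23 ± 0.515 and 52.3 ± 40.8 CPM. Ighg2b had 0.600 ± 0.789 and 273 ± 326 CPM. The mean was 5.27 without WT replicate 3. Mast cell and eosinophil genes had a mean of 1.04 over 10 members (camera FDR 0.0368; adjusted p = 0.676 with an estimated correlation), with 1, the tryptase Tpsab1, rising when adjusted over the list alone from 0.312 ± 0.329 to 11.5 ± 2.97 CPM. Mcpt1 and Cma1 had log2 fold changes of 1.69 ± 1.19 and 0.99 ± 0.82. Mcpt1 had 0.82 without Thbs2KO replicate 1, and Cma1 had 0.46 without WT replicate 1 and 2.03 without WT replicate 3. That list did not pass without WT replicate 1 (0.72), Thbs2KO replicate 1 (0.95) or Thbs2KO replicate 2 (1.06), or with a prior count of 0.5. Dendritic cell markers did not pass, with a mean of 0.10, a median of 0.06, the opposite direction in camera and a camera FDR of 0.624; the mean was -0.57 without Thbs2KO replicate 1.

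Fibroblast markers were moderately higher on average, while extracellular matrix genes showed no shift past the threshold. Fibroblast scores overlapped between the groups, at 5.55, 6.12 and 6.52 in WT and 7.21, 6.27 and 6.98 in Thbs2KO tumours. The fibroblast list had a mean log2 fold change of 0.88 over 23 members, 0 of which passed alone (camera FDR 0.00454; adjusted p = 0.675 with an estimated correlation), and did not pass without WT replicate 1 (0.68). Clec3b, Pi16, Cd34 and C3 had log2 fold changes of 4.42 ± 1.01, 3.06 ± 0.88, 0.98 ± 0.29 and 2.71 ± 0.88 (SE). Pi16, a marker of adventitial fibroblasts, had 348, 43.8 and 85.0 CPM in Thbs2KO tumours. Without Thbs2KO replicate 1 the log2 fold changes of Pi16, C3 and Col14a1 were 1.76, 1.37 and 0.34. Extracellular matrix genes had a mean of -0.04 over 38 members and 0 passed alone (camera FDR 0.284); the list passed downward without Thbs2KO replicate 2 (-0.32). Its mean was above 0 without WT replicate 3 (0.06), without Thbs2KO replicate 3 (0.13) and with the epithelium covariate (0.29). Eln (elastin) had 184 ± 61.5 and 52.2 ± 45.9 CPM, Fmod 10.6 ± 4.59 and 31.0 ± 12.4 CPM, Col14a1 53.6 ± 8.43 and 124 ± 98.5 CPM and Col6a2 699 ± 192 and 458 ± 114 CPM. With 1 tumour left out, the log2 fold change ran from -2.75 to -1.33 for Eln and from -0.83 to -0.36 for Col6a2. Collagen I chain Col1a1, chosen after its values were seen, had 3830 ± 747 and 3869 ± 832 CPM.

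Other stromal lists did not pass camera. They were myofibroblastic fibroblasts (mean -0.20, median 0.10, FDR 0.495), matricellular proteins (0.29, FDR 0.624), matrix proteases and crosslinking enzymes (0.49, FDR 0.0587), the TGF-beta response (0.07, FDR 0.917, opposite direction in camera), pericytes (0.46, FDR 0.362) and lymphatic endothelium (0.15, FDR 0.917). The direction of the TGF-beta list turned with library size as the only scaling (-0.01), without WT replicate 1 (-0.11) and without Thbs2KO replicate 3 (-0.09). The implanted tumour cells carried a Tgfbr2 mutation, and bulk RNA does not separate their TGF-beta genes from those of host cells. Matrix proteases passed upward with library size only (0.42), with no expression filter (0.50), with the epithelium covariate (0.49), and without WT replicate 2 (0.64), WT replicate 3 (0.63) or Thbs2KO replicate 1 (0.59); the mean was 0.27 without WT replicate 1 and 0.33 without Thbs2KO replicate 3. Lymphatic endothelium turned without WT replicate 1 (-0.24) or Thbs2KO replicate 1 (-1.60), and myofibroblastic fibroblasts without Thbs2KO replicate 1 (0.03). Without Thbs2KO replicate 3 the pericyte mean was 0.0054 and the matricellular mean 0.02. Within the matricellular list Thbs3, a relative of Thbs2, rose when adjusted over the list alone, from 20.2 ± 1.75 to 41.5 ± 7.01 CPM, as did Ccn3, from 7.03 ± 3.65 to 87.8 ± 91.0 CPM; the log2 fold change of Ccn3 was 3.64, and 2.36 without Thbs2KO replicate 3. In the TGF-beta list the secreted protein gene Tgfbi rose from 154 ± 40.8 to 459 ± 111 CPM and the pathway inhibitor Smad6 fell from 27.1 ± 6.71 to 10.7 ± 3.32 CPM by the same criterion. Endothelial and angiogenesis genes had a mean of 0.73 over 27 members, 0 of which passed alone (camera FDR 0.00251; adjusted p = 0.694 with an estimated correlation). Eng and Plvap had log2 fold changes of 0.86 ± 0.26 and 1.10 ± 0.40, while Sox17 had -1.43 ± 0.32. The list did not pass without WT replicate 1 (0.48). Its tumour scores overlapped, at 3.93 to 5.14 in WT and 5.11 to 5.28 in Thbs2KO tumours.

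Wnt target and intestinal stem cell genes were lower in Thbs2KO tumours. Of 20 measured members, 18 had a lower mean, 1 (Ascl2) fell when adjusted over the list alone and 0 passed over all genes. The mean log2 fold change was -0.81 (camera FDR 3.05e-04; adjusted p = 0.675 with an estimated correlation), and -0.52 without WT replicate 1. The Wnt feedback genes Notum and Nkd1 had -1.24 ± 0.34 and -2.04 ± 0.65 (log2, SE), and Tnfrsf19 had -1.07 ± 0.36. Nkd1 had -0.91 without WT replicate 1. The stem cell marker Lgr5, chosen after its values were seen, had 8.48 ± 1.72 and 11.5 ± 2.12 CPM. Beside this, the tumour epithelium list had a mean of -0.38 over 20 members and did not pass (FDR 0.122); it passed downward without WT replicate 1 (-0.47) or Thbs2KO replicate 2 (-0.49), and was at -0.20 without WT replicate 3 and -0.23 without Thbs2KO replicate 3. Cell cycle genes had a mean of 0.32 over 30 members, 0 of which passed alone (camera FDR 0.00549; adjusted p = 0.773 with an estimated correlation); Cdk1 had 39.6 ± 5.63 and 57.7 ± 8.06 CPM, and the mean was 0.03 without Thbs2KO replicate 1. Regenerative epithelium (mean 0.12, FDR 0.109), MAPK output (-0.24, FDR 0.218), p53 target (0.07, FDR 0.703) and hypoxia genes (0.03, FDR 0.917) did not pass, and p53 targets and hypoxia genes turned downward with library size as the only scaling (-0.05 for hypoxia). Regenerative epithelium passed upward without WT replicate 3 (0.39), with no expression filter (0.30) and with the epithelium covariate (0.35), and was at -0.09 without WT replicate 1. Hypoxia genes passed downward without WT replicate 1 (-0.24), and p53 targets were at -0.02 without that tumour. The implanted tumour cells carried a Trp53 mutation, and bulk RNA does not separate their p53 targets from those of host cells.

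**Figure D3:**
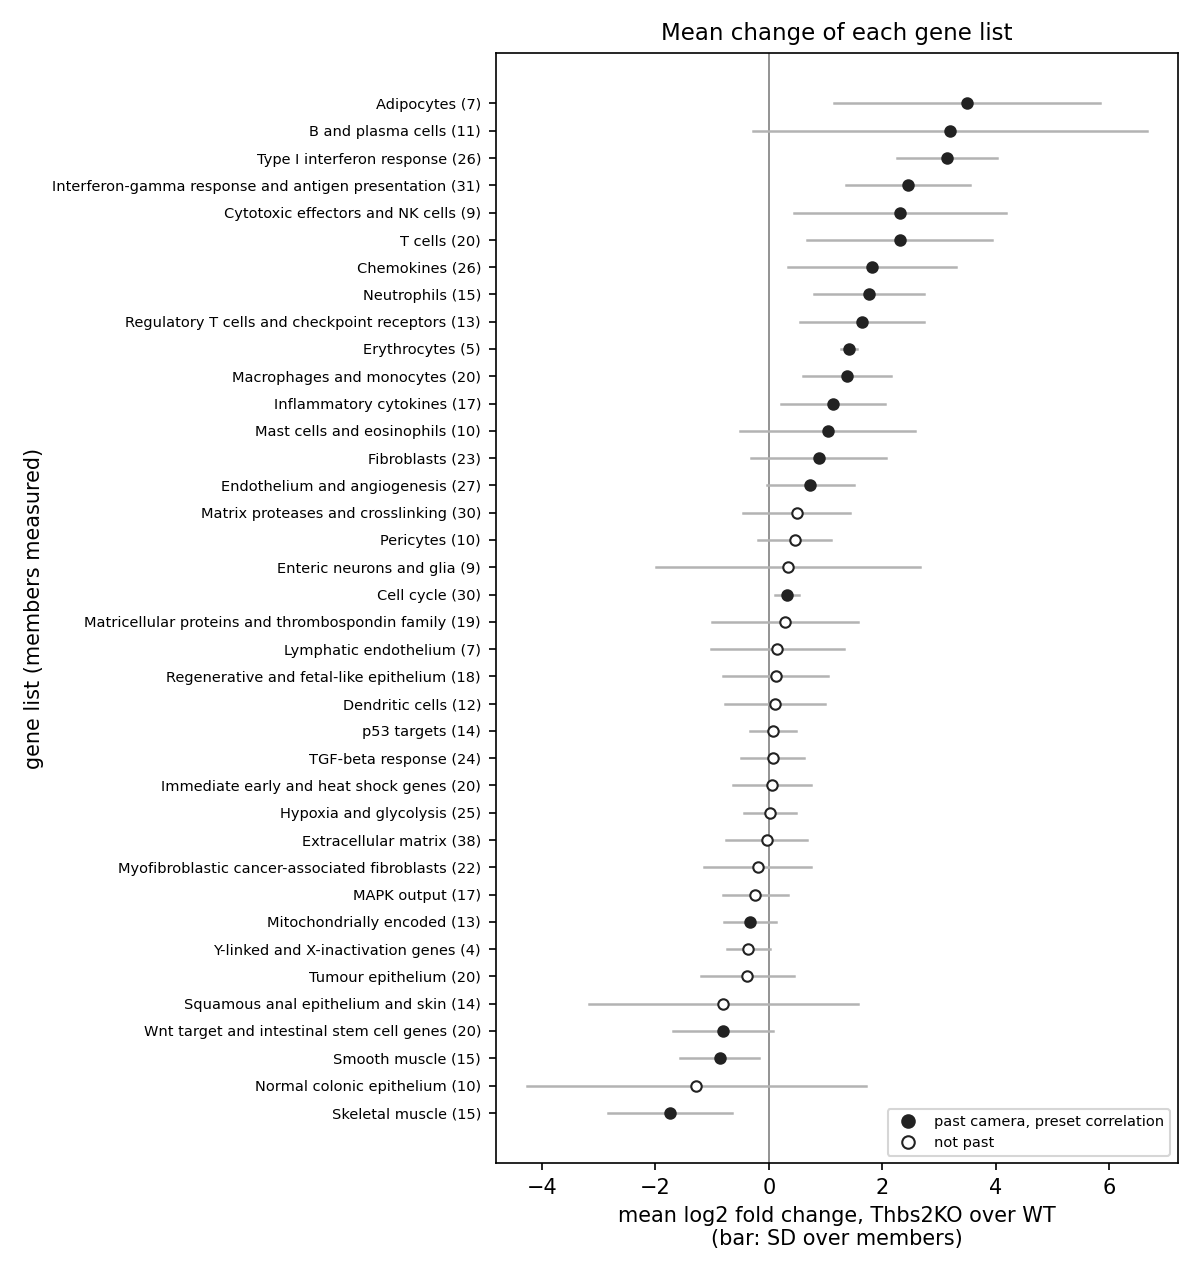
Mean log2 fold change of each of the 38 gene lists, Thbs2KO over WT, with bars of 1 SD over members; filled points passed camera with the preset correlation. Type I interferon genes lie at 3.15 and Wnt target genes at -0.81, and extracellular matrix genes lie near 0 at -0.04.

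Adipocyte and erythrocyte genes were higher by list score in each Thbs2KO tumour than in any WT tumour, while the scores of both muscle lists overlapped between the groups. Adipocyte genes had a mean log2 fold change of 3.49 over 7 members, 4 of which rose when adjusted over the list alone (camera FDR 3.79e-05; adjusted p = 0.648 with an estimated correlation). The adipokine gene Adipoq had 3 counts in WT and 293 in Thbs2KO libraries, a ratio of 82.0 with a counting interval of 27.8 to 400, and Cidec and Cfd had 5.79 ± 0.99 and 5.02 ± 1.12. Haemoglobin and other erythrocyte genes had a mean of 1.41 over 5 members, 0 passing alone (camera FDR 0.00108; adjusted p = 0.675 with an estimated correlation), and 2.46 without WT replicate 3. Skeletal muscle genes had a mean of -1.74 over 15 members, 0 passing alone (camera FDR 0.00525; adjusted p = 0.773 with an estimated correlation), and did not pass without WT replicate 2 (-0.78) or Thbs2KO replicate 2 (-1.20). Smooth muscle genes had a mean of -0.87 over 15 members, with 1, Pgm5, falling when adjusted over the list alone (camera FDR 0.0126; adjusted p = 0.773 with an estimated correlation). That list did not pass without WT replicate 2 (-0.69), WT replicate 3 (-0.55) or Thbs2KO replicate 1 (-0.63), and had -1.47 without Thbs2KO replicate 3. Normal colonic epithelium (mean -1.28, FDR 0.917), squamous epithelium (-0.81, FDR 0.917) and enteric neurons and glia (0.33, FDR 0.644) did not pass. The mean of enteric neurons and glia was 0.10 without Thbs2KO replicate 3. Without WT replicate 3 the normal colon mean was 0.39 and the squamous mean 0.66, and the squamous list then passed upward, as it did with the epithelium covariate (0.33). In the normal colon list Agr2 and Fcgbp fell and Reg3g rose when adjusted over the list alone, as did Muc2 downward and Slc37a2 upward, both chosen after their values were seen. Fcgbp was at 42.4 CPM in WT replicate 3 and at most 1.28 CPM in the other 5 tumours, and its log2 fold change went from -5.22 to -1.53 without that tumour. Muc2 was at 30.4 CPM there and at most 1.78 CPM elsewhere. The squamous gene Krt10 was at 254 CPM in WT replicate 3 and at most 1.61 CPM in the other 5 tumours.

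Mitochondrially encoded genes had a mean log2 fold change of -0.33 over 13 members, 0 of which passed alone (camera FDR 0.00724; adjusted p = 0.675 with an estimated correlation). The mean was -0.23 and did not pass without Thbs2KO replicate 1, and was -0.67 without Thbs2KO replicate 3. Immediate early and heat shock genes did not pass (mean 0.05, FDR 0.624; -0.02 with library size only and -0.14 without WT replicate 1). The Y-linked gene Ddx3y was at 47.1 to 83.9 CPM in all 6 tumours and Xist, below the expression filter, at 0.557 CPM or less. The sex-linked list did not pass (mean -0.36, FDR 0.352). Its mean ran from -0.59 to -0.20 with 1 tumour left out. In total 20 of 38 lists passed camera, 16 higher and 4 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.65) and with fry 0 passed (smallest adjusted p = 0.074). For 7 lists the mean, the median and camera differed in direction: myofibroblastic fibroblasts, dendritic cells, p53 targets, normal colonic epithelium, hypoxia, squamous epithelium and TGF-beta response.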

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

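The removal of 2 ribosomal RNA-like genes, the other tests of the Thbs2 level (DESeq2, limma-voom and upper quartile factors) and the counts of list members without each tumour were chosen after seeing the data; all other alternatives were planned. The count of changed genes (11; 10 higher, 1 lower) was 116 (108 and 8) with no filter, 4 (4 and 0) with a mean of at least 1 CPM, 84 (78 and 6) at FDR under 0.10, 0 (0 and 0) with the epithelium covariate, 6 (5 and 1) in limma-voom, 100 (93 and 7) with sample weights and 989 (754 and 235) in DESeq2. Of the 11 genes, 11 were also called in DESeq2, with sample weights, with no filter, with RLE or upper quartile factors and without the ribosomal RNA-like genes, 9 with library size only, 5 in limma-voom, 4 with the CPM minimum and 0 with the covariate. Leaving out 1 tumour gave 0 to 26 genes, 0 to 26 higher and 0 to 0 lower; fewer samples are part of that, and the cause was otherwise not tested. Whether replicate numbers pair the samples stays open. Same-numbered tumours correlated at 0.132, -0.0715 and 0.312 after removing group means, and some but not all tumours correlated best with their own number. With so few tumours per group the deviations from a group mean must cancel out, so these correlations cannot decide it. Pairing itself was not tested. The replicate block gave 210 genes (188 higher, 22 lower) and the same 20 lists in number, moved the Thbs2 level past the threshold at -2.48, and turned dendritic cells (-0.17) and lymphatic endothelium (-0.85).

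The Thbs2 level passed at -3.07 with sample weights and -2.40 in DESeq2, and stayed negative in all 17 alternatives (-3.08 to -2.14). With an estimated correlation and with fry, 0 lists passed (0 higher, 0 lower). Both allow for genes of a list moving together, but why the lists no longer passed was not tested. The means were then unaltered: type I interferon 3.15, interferon-gamma 2.46, T cells 2.31, cytotoxic 2.31, macrophages 1.38, fibroblasts 0.88, endothelium 0.73 and Wnt targets -0.81. With 1 tumour left out, 2 to 6 lists were lower. The means then ran from 0.79 to 2.72 for cytotoxic genes, 0.59 to 1.16 for fibroblasts, 0.48 to 1.02 for endothelium, -0.32 to 0.13 for extracellular matrix, -0.57 to 0.37 for dendritic cells, -0.42 to 0.033 for myofibroblastic fibroblasts, -0.11 to 0.23 for TGF-beta response, -1.60 to 0.75 for lymphatic endothelium, -0.088 to 0.39 for regenerative epithelium, -1.58 to 0.39 for normal colon, -1.18 to 0.66 for squamous epithelium, -0.24 to 0.22 for hypoxia, -0.022 to 0.14 for p53 targets and -0.14 to 0.18 for immediate early genes.

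Directions turned with library size only for the list TGF-beta response (-0.0067), hypoxia (-0.052), the list p53 targets (-0.00092) and immediate early genes (-0.017); with the epithelium covariate for extracellular matrix (0.29), squamous epithelium (0.33), hypoxia (-0.087) and Reln (0.62); with no filter for enteric neurons and glia (-1.03); and in limma-voom for Mcpt1 (-0.096). Krt10 ran from -7.19 to 2.37 and Ddx3y from -0.28 to 0.043 with 1 tumour left out. The cause of these turns was not tested. Library size only moved the median of all genes by -0.077. In the simulation 10.4% of 2-fold changes were recovered, so most changes of that size would be missed. The simulated shares may be too high for these tumours. Of the real type I interferon genes, 3 of 26 passed over all genes tested, at a mean of 8.85-fold. In the simulation 87.9% of 8-fold changes were recovered. The effect of depth alone was not tested.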

Other observations

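All tests in this part were chosen after the result was seen, except the share of pseudogenes among genes near absent in 1 genotype. A scan of 233 gene families, formed from shared symbol roots with at least 8 tested members, found 10 higher and 5 lower in Thbs2KO tumours with camera at the preset correlation; with an estimated correlation 0 passed. Among families not covered by the lists were the Toll-like receptors. All 11 had a higher mean in Thbs2KO tumours (mean log2 fold change 1.09, FDR 0.00109), and 5 rose when adjusted over the family alone. Members named here were chosen after their values were seen. Tlr7, a sensor of single-stranded RNA, and Tlr2, a sensor of bacterial lipoproteins, had log2 fold changes of 1.40 and 1.74. All 21 Clec genes, which encode C-type lectins of myeloid and other cells, had a higher mean (1.34, FDR 1.13e-05), with 6 rising when adjusted over the family alone. In the Parp family 10 of 12 members had a higher mean (mean 0.92, FDR 0.0116), and 6 rose when adjusted over the family alone. Parp9 and Parp12, which interferon induces, had 1.94 and 2.14, while Parp1, the DNA repair enzyme, had -0.45.

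Among the 5 lower families, the Zfp zinc finger genes had a mean of -0.17, with a lower mean in 236 of 345 members and 0 passing over the family alone (FDR 0.00151), and group scores overlapped. Myosin heavy chains had a mean of -2.25, with a lower mean in all 9 and 1 passing over the family alone (FDR 0.0164), and their scores overlapped too. The Ttll tubulin ligases (mean -0.49, FDR 0.0393) and the Cbx chromobox genes (-0.43, FDR 0.0465) had a lower mean in all 9 and all 8 members, with 0 passing over either family alone, and their scores did not overlap.

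The first pattern weighed is the higher type I interferon genes. A larger share of macrophages like those of WT tumours, as the whole cause, is only weakly argued against. The interferon score rose by 1.78 more than the macrophage score, with an SE of 0.653 from 3 tumours per group. The difference of scores in Thbs2KO replicate 3 (-1.44) was close to that in WT replicate 1 (-1.45). Score comparisons of this kind cannot weigh added cells that carry more interferon-induced RNA than those of WT tumours. A larger share of T cells is argued against in Thbs2KO replicates 2 and 3. There the interferon score minus that of CD3 and T cell receptor constant genes was 4.95 and 4.98, against 3.17 to 3.47 in WT tumours. Their mean was 1.62 above the WT mean with an SE of 0.0915. These 2 tumours were grouped after the values were seen, and that SE does not cover this choice. A larger share of T cells stays open in Thbs2KO replicate 1, at 3.31 or -0.029 from the WT mean. Over all 3 Thbs2KO tumours the difference was 1.07 with an SE of 0.559. Alleles linked to the Thbs2 locus stay open. Of the 26 genes, 0 lie within 20 Mb of it, but a linked allele could act on all of them through a shared signal. Host genotype and housing or infection were not tested. No other list was weighed for linkage. The named genes Prr18, Tpsab1, Pi16 and Psmb8 start inside that window on chromosome 17, at 8337459, 25343245, 29317680 and 34197721. Psmb8 belongs to the interferon-gamma list. Of that list only Psmb8, Psme1, Psme2 and B2m were looked up by position, so further members may lie in the window. Linked alleles stay open for these genes and for the interferon-gamma list too.

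The second pattern is that T cell and cytotoxic genes were highest in Thbs2KO replicate 1, where 4 CD3 genes summed to 45.8 CPM against 8.04 and 3.03 in the other Thbs2KO tumours. A mislabelled sample is argued against by Thbs2, at 21.24% of the lowest WT tumour. Lymphoid follicles taken with the tumour stay open: 4 B cell genes summed to 11.91% of the CD3 genes there, but at 5.46 CPM they were also highest in this tumour, against 0.777 to 2.98 CPM in the other 5. A difference in infiltration between Thbs2KO tumours was not tested.

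The third pattern is a set of 31 genes with under 0.5 CPM in every tumour of 1 genotype and at least 1 CPM in every tumour of the other, 25 present in Thbs2KO and 6 in WT tumours. Examples, chosen after their values were seen, are Ifi44l, at 0 CPM in all WT tumours, and Rdh16f1. The set also holds Adipoq and Cidec of the adipocyte list, which was higher in Thbs2KO tumours, and Mpz of the glia list, which did not pass. Differences in cell content or in the interferon response were not tested as a cause for the set. Alleles within 20 Mb of Thbs2 that act on their own genes account for none of the 31, since 0 lie there. That window held 391 of the 15382 tested genes, so few of 31 would fall in it by chance, and the 0 is no measure of linkage. Tpsab1, inside the window, missed the set only through WT replicate 2, at 0.655 CPM. Guca1b and Kcnk12 of the set lie on chromosome 17 beyond the window, so alleles linked over a longer distance stay open for them. Reads shared between near-identical copies stay open: 19.35% were pseudogenes, under the 25% set beforehand as a bound against it. That bound ignored the 3.18% among all tested genes (two-sided Fisher's exact p = 3.75e-04, run afterwards). It also ignored coding genes whose spans overlap, such as Rdh1 and Rdh16f1. For chance, 1 of the 10 splits of the 6 tumours, the real one, gave as many genes, the highest other split gave 20, and 10 splits are too few for a share under 0.05; differences in strain background away from Thbs2 were not tested.

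For the gene test, 1 of the 10 splits, the real one, gave as many as 11 genes, and the highest other split gave 0. For the gene test, 10 splits are too few for a share under 0.05. For the list tests, 5 of the 10 splits gave at least the 20 lists of the real one, and the highest other split gave 25. The number of lists past camera at the preset correlation therefore did not set the real grouping apart from other groupings.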
